A study of Arabidopsis thaliana with 32 samples.

How the data were processed

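Transcript levels were measured on 32 Affymetrix arrays in total RNA from aerial parts of Arabidopsis thaliana. The 32 arrays fall into 8 groups of 4, made of 4 lines (the Col-0 wild type, here wt, and the mutants bri1-301, ces-D and qM) and 2 temperatures (4°C or 21°C for 3 d). Groups and replicate numbers were taken from the sample labels. The labels do not say that replicates came from separate batches of plants, so p-values measure only the spread between these samples, which may be partly technical.

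Per the labels' protocols, the RNA was converted to biotin-labelled target with the manufacturer's whole-transcript kit. The values deposited by the authors are on a log2 scale. They were summarised and normalised with RMA, per the submitters' processing notes; the version of RMA is not given in the sources used here. RMA subtracts background, brings all arrays to the same distribution and combines the probes of a probe set, so differences that affected all genes of an array alike would have been removed before deposit. No scanner files, scan dates or slide positions were used here, and signal over background could not be assessed. For arrays, precision is limited by their number, 4 per group.

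The value table held 38408 probe sets. A probe table from the platform annotation named 17504 of them: 16746 with 1 gene and 758 with several. The other 20904 probe sets are unnamed here, which does not mean that they lack a gene. Only probe sets with 1 gene were tested. Where a gene had several, the one with the highest mean over all 32 arrays was kept, which dropped 192 and left 16554 genes. Of these, 16418 matched a locus of the reference gene table (assembly TAIR10.1), which was used for names and for the order of neighbouring genes only, and 1792 had a symbol other than a locus name. Genes without a symbol are given by their locus name.

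The following choices were made before the data were examined. Expression was compared with limma 3.58.1 in R 4.3.3, on the deposited log2 values, in 1 linear model of 8 group means over all 32 arrays with moderated variances (lmFit, contrasts.fit and eBayes with default settings) and two-sided tests. There were 13 contrasts: 4°C minus 21°C within each of the 4 lines, each mutant minus wt at 21°C and at 4°C, and the interaction of line and temperature for each mutant (its cold response minus that of wt). P-values were adjusted by the Benjamini-Hochberg method over the 16554 genes within each contrast, with a threshold of 0.05. Counts were also made at a change of at least 2-fold. Log2 differences are given with the standard error (SE) of the model, and group levels as the mean ± SD of 4 arrays.

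Also fixed beforehand were 25 gene lists with 307 entries (306 distinct genes). Only 37 of these genes were measured by a probe set with 1 named gene, and 9 lists had no measured gene. The 7 lists with at least 3 measured genes were tested in all 13 contrasts (91 tests, adjusted together) with camera of limma, using a preset correlation between genes of 0.01. They were cold-regulated (COR) genes, regulators upstream of the CBF genes, brassinosteroid-induced growth genes, flavonoid and anthocyanin genes, nuclear photosynthesis genes, jasmonate genes and reference genes. Camera was repeated with a correlation estimated per list, and fry of limma was run beside it.

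Genes were named by a rule set at the same time. CES, BEE1, BEE2, BEE3, BRI1, CBF1, CBF2, CBF3, COR15A, COR78, DWF4, CPD and BR6OX2 were to be reported wherever measured. For the wt cold response the rule took the 10 largest rises and 10 largest falls past the threshold whose 4 arrays of one group all lay above the 4 of the other. For each mutant against wt it took the 5 largest in each direction in the same way, and for each interaction the 5 largest in each direction without the condition on separate arrays. From each list it took up to 4 members with the largest change past the threshold. Of the genes to be reported always, CES and COR15A were measured under a single gene name and the others are not analysed here.

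The pipeline was tested on simulated data made from the real mean and residual spread of each gene, in which 50 genes each were changed by known log2 amounts among 16554. For ces-D against wt at 21°C it recovered 54% of genes changed by 0.5, 96% of those changed by 1 and 100% of those changed by 2 or 3, with 10 false calls among 185. For the cold response of bri1-301 the shares were 44%, 96%, 100% and 100%, with 4 false calls among 174. For the interaction of ces-D they were 18%, 76%, 100% and 100%, with 4 false calls among 151.

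Alternatives planned beforehand were a replicate block, array weights, an intensity trend with robust variances, an ordinary t-test, a fit of only the compared groups, median centring, repeated quantile normalisation, a filter on dim genes, the mean of all probe sets of a gene, all 38408 probe sets, stricter thresholds and leaving out each array in turn. Pairs of comparisons against the same wt arrays were set beside 100 simulations of unchanged groups sharing those arrays, beside the overlap of independent lists, and beside values from split wt arrays. Other choices were made after the data were seen. These included leaving the array labelled wt 4°C replicate 4 out of the contrasts that do not use it (which changes their shared spread), applying the naming rule to the fit without that array, counting genes shared by the lines without it, counting the genes shared by bri1-301 and qM in ces-D with the wt 21°C arrays split and in simulated unchanged groups, and testing 37 gene families that share the letters of their symbol (at least 8 genes each, the plastid-encoded genes among them). They also included the tests of the source of that array, of the placement of ces-D genes along chromosomes and of probe sets shared by neighbouring copies. The count of such ces-D genes next to CES was chosen then too.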

Results

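Transcript levels were compared in aerial parts of Arabidopsis thaliana of 4 lines kept at 4°C or at 21°C for 3 d. The lines were wt (Col-0), bri1-301 (a mutant of the brassinosteroid receptor gene BRI1), ces-D (a line with a dominant allele of CES, which encodes a bHLH transcription factor) and qM (which carries mutations in CES and its 3 relatives BEE1, BEE2 and BEE3, the CES allele being ces-2). Plants were grown on soil for 21 d in long days and then treated under continuous light at either temperature. The series asked how brassinosteroids take part in freezing tolerance without and with a period of cold. There were 4 arrays per line and temperature, 32 in all, and 16554 genes were tested. The array medians over these genes lay between 3.75 and 3.84 on the log2 scale. Signal over background was not assessed, so the size of any difference from or to a level near or below these medians is uncertain. The first principal component held 45.8% of the variance and separated 15 of the 16 arrays labelled 4°C, at 22.1 to 38.1, from the 16 arrays labelled 21°C, at -28.5 to -21.5. The second held 15.5% and separated the 8 ces-D arrays, at 24.2 to 31.7, from the 24 others, at -15.7 to -4.71.

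The array labelled wt 4°C replicate 4 stood apart from its group. Its first component was -25.4, within the range of the arrays labelled 21°C. Its mean over the 6 measured COR genes was 5.22, below the 9.56 of the lowest other array labelled 4°C and the 6.67 of the highest array labelled 21°C. AT3G01345 was at 10.2 on this array, against 9.77 to 10.8 on the 8 bri1-301 arrays and at most 5.16 on the other 23. AT5G41740, which encodes a TIR-NBS-LRR protein, was at 8.10 on it and at 4.63 to 5.42 on the other 7 wt arrays. QQS was at 3.99 on it, above the 2.44 to 3.73 of the bri1-301 arrays and below the 4.29 to 5.66 of the other wt arrays over both temperatures. At 21°C alone these ranges were 3.23 to 3.73 and 5.27 to 5.66. The array correlated with the other 3 arrays of its group at a mean r of 0.974 and with the 4 wt 21°C arrays at 0.992, across genes, which are not independent replicates. It was kept in its labelled group, and the values without it, a choice made after the data were seen, stand beside the counts of genes past the threshold.

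**Figure D1:**
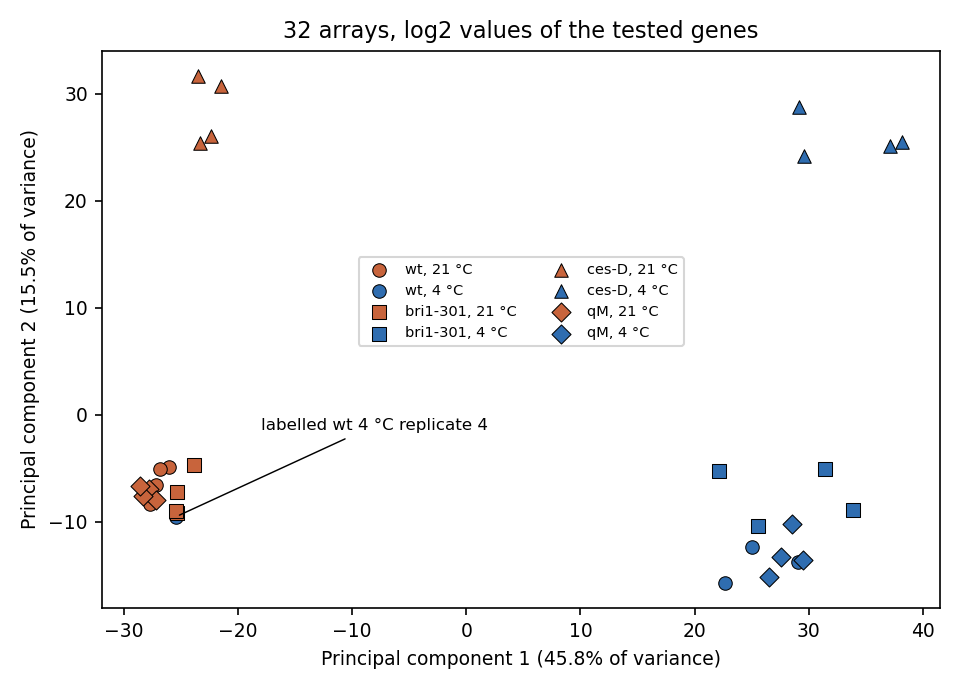
The 32 arrays by their first (45.8% of the variance) and second (15.5%) principal component over the 16554 tested genes, coloured by temperature with a symbol per line. The array labelled wt 4°C replicate 4 lies at -25.4 on the first component, among the 16 arrays labelled 21°C.

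CES was measured first, because the lines alter it. In ces-D its transcript was at 11.0 ± 0.05 (SD, n = 4) at 21°C and 11.0 ± 0.21 at 4°C, against 2.47 ± 0.69 and 2.06 ± 0.22 in wt, a log2 difference of 8.57 ± 0.48 (SE, limma adjusted p = 8.05e-14) and 8.96 ± 0.48 (adjusted p = 2.4e-14). All 4 ces-D arrays lay above all wt arrays at both temperatures. In qM it was at 1.96 ± 0.29 at 21°C and 2.00 ± 0.09 at 4°C, and the difference from wt did not pass at 21°C (-0.51, limma adjusted p = 0.999). The wt level is itself near the lower end of the arrays' scale, where signal over background was not assessed, so the size of the difference in ces-D is uncertain. Where the probe set lies relative to the ces-2 lesion is not known here, so CES does not check the qM label. In bri1-301 CES was at 3.43 ± 1.97 at 21°C, with 3.87 and 6.05 on replicates 1 and 3 and 1.92 and 1.90 on replicates 2 and 4, and at 2.03 ± 0.14 at 4°C. Its cold response in bri1-301 passed (-1.40 ± 0.48, limma adjusted p = 0.0271), but not when bri1-301 21°C replicate 1 or 3, or bri1-301 4°C replicate 1 or 2, was left out (-1.37 to -0.53, adjusted p from 0.0574 to 0.234), and it was not shown to differ from that of wt (interaction -0.99, adjusted p = 0.518). BEE1, BEE2, BEE3 and BRI1 are not analysed here.

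Cold raised the transcripts of the COR genes, which protect cells against freezing, in wt and in each mutant. In wt COR15A, which encodes a cryoprotective protein of chloroplasts, went from 7.35 ± 0.30 to 10.5 ± 2.51 (SD, n = 4), an 8.66-fold rise (log2 3.11 ± 0.57 SE, limma adjusted p = 0.000305). It was higher on 3 of the 4 wt 4°C arrays, at 11.7 ± 0.03 (n = 3), and at 6.69 on replicate 4, without which the rise was 20.7-fold (4.37 ± 0.11, adjusted p = 6.77e-23). The dehydrin gene LTI30 rose by 5.28 ± 0.77 on the log2 scale (limma adjusted p = 3.37e-05), and by 6.97 ± 0.15 without that array, from a 21°C level of 1.99 ± 0.21 near the lower end of the scale, so that the size and its place among the largest rises are uncertain. COR15B (3.63), KIN1 (2.98), KIN2 (2.82) and the dehydrin gene COR47 (1.43) also rose, with limma adjusted p between 4.37e-05 and 0.000309, and by 4.80, 3.94, 3.81 and 1.96 without that array. All 6 COR genes passed, as did 6 adjusted over the list alone. The list's median was 3.05 (camera adjusted p = 1.03e-06). Its adjusted p = 0.281 with an estimated correlation, and without the array labelled wt 4°C replicate 4 this was 3.53e-06, with a median of 4.16.

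In wt 3554 genes passed between 4°C and 21°C, 1732 higher and 1822 lower at 4°C, of which 303 changed at least 2-fold (132 higher, 171 lower). Without the array labelled wt 4°C replicate 4 there were 4972 (2453 higher, 2519 lower), 3425 of them among the 3554, with 627 at least 2-fold (265 higher, 362 lower). With the arrays centred on their median higher genes were the more frequent (2050 higher, 1642 lower), and without wt 4°C replicate 3 there were 2210. Among genes whose 4 arrays of one temperature all lay above the 4 of the other, the largest rises were those of AT3G28310 (3.19 ± 0.51, limma adjusted p = 8.56e-05), AT1G70640 (2.46), AT5G40180 (2.29), AT1G11210 (2.12 ± 0.28, adjusted p = 1.58e-05), AT1G02460, AT4G01870, AT5G13370, AT1G51090, AT5G61820 and the glutamate receptor-like gene ATGLR1.2 (1.64 ± 0.27, adjusted p = 9.66e-05). The largest falls were those of AT5G44540 (-2.65 ± 0.36, limma adjusted p = 2.34e-05), the jacalin-related lectin gene JAL23 (-2.58), AT4G21870 (-2.29), AT5G40450 (-2.18), the wax ester synthase gene WSD1 (-2.10 ± 0.19, adjusted p = 6.51e-08), AT1G68875, AT2G20870, AT1G25230, AT4G23680 and ATA27. The fixed list of 7 floral organ markers had 0 measured genes, so differences between groups in the organs or stage sampled could not be assessed with it. AT3G28310 was at 4.2 without the array labelled wt 4°C replicate 4, AT1G70640 at 3.16, AT5G40180 at 2.92, JAL23 at -3.29, AT4G21870 at -2.92 and AT5G40450 at -2.82. The same rule without it gave LTI30 (6.97), AT4G01985 (5.48), AT1G16850 (5.27), COR15B (4.80) and COR15A (4.37) as the largest rises. The largest falls were then AT4G31354 (-2.87), AT1G28660 (-2.86), the glucosyltransferase gene UGT74D1 (-2.85), AT3G46880 (-2.82) and AT4G31351 (-2.75).

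Of 4 measured brassinosteroid-induced growth genes, 3 fell in the cold in wt, and 3 adjusted over the list alone: the expansin gene EXPA8 (-1.61 ± 0.32, limma adjusted p = 0.000726), EXO (-0.87, adjusted p = 0.00309) and the expansin gene EXPA4 (-0.47, adjusted p = 0.0319). EXPA4 lost its call without wt 4°C replicate 1, 2 or 3 or wt 21°C replicate 3 or 4 (-0.47 to -0.38, adjusted p from 0.0641 to 0.133), and the auxin-induced gene AT2G18010 was at 0.03 (adjusted p = 0.92). The list's median was -0.67 (camera adjusted p = 0.0337; without wt 4°C replicate 3, 0.0526), and adjusted p = 0.281 with an estimated correlation. UGT73C6, whose glucosyltransferase can inactivate brassinosteroids, fell by 1.21 ± 0.14 (limma adjusted p = 2.39e-06). Of the signalling genes, BIM1, which encodes a bHLH partner of BES1, fell by 0.55 (adjusted p = 0.000908), and the receptor gene BRL1 was at 0.42 (adjusted p = 0.144). Of 3 measured nuclear photosynthesis genes, 2 fell, and 3 adjusted over the list alone. These 2 were the antenna protein genes LHCB4.2 (-0.59, limma adjusted p = 0.00869) and LHCB4.1 (-0.36, adjusted p = 0.00931), and the Rubisco activase gene RCA was at -0.23 (adjusted p = 0.061). LHCB4.2 lost its call without wt 4°C replicate 3 (-0.43, adjusted p = 0.0667). That list's median was -0.36 (camera adjusted p = 0.0337; without wt 4°C replicate 3, 0.0811), and adjusted p = 0.396 with an estimated correlation.

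Among lists with 1 or 2 measured genes, the clock gene GI rose by 0.82 ± 0.15 in wt (limma adjusted p = 0.000392), the zinc-finger gene STZ by 0.95 (adjusted p = 0.00236) and the senescence-associated factor gene WRKY6 by 0.61 (adjusted p = 0.00665). The sucrose phosphate synthase gene ATSPS4F rose by 0.73 (limma adjusted p = 0.00884), a call lost without wt 4°C replicate 1 (0.55, adjusted p = 0.056). SAG101, which encodes a partner of the immune regulator EDS1, was at 0.20 (adjusted p = 0.143). Of 3 genes upstream of the CBF genes, PIF7 was at 0.26 (limma adjusted p = 0.0315, and from 0.0507 to 0.126 without wt 4°C replicate 1 or 2 or wt 21°C replicate 2 or 3), EIN3 at -0.23 (adjusted p = 0.0505) and the SUMO ligase gene SIZ1 at 0.08 (adjusted p = 0.442). The list's median was 0.08 (camera adjusted p = 0.881). The jasmonate genes JMT (-0.32), PDF1.2 (-0.33) and THI2.1 (-0.10) did not pass, and their list's median was -0.32 (camera adjusted p = 0.432). The flavonoid genes DFR (-0.17, limma adjusted p = 0.783) and UF3GT (0.43, adjusted p = 0.318) did not pass. The reference genes PEX4, AT4G34270 and AT2G28390 had a median of 0.00 (0.00376, with the test's direction downward, camera adjusted p = 0.861). The root expansin genes EXPA7 (0.05 in the cold response of wt) and EXPA18 (0.32) passed in none of the 13 contrasts. The reference gene AT2G28390 was higher in the cold in ces-D (0.30, limma adjusted p = 0.00951). In other list tests that did not pass, the median and the direction of the test also differed in sign for the reference genes in the cold response (0.03) and interaction (-0.05) of bri1-301 and in qM at 4°C (-0.01), the genes upstream of the CBF genes in qM at 4°C (0.02) and the photosynthesis genes in the interaction of qM (-0.02).

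The mutants also responded to cold. COR15A rose 40.1-fold in bri1-301 (log2 5.33 ± 0.57, limma adjusted p = 2.53e-07) and 38.9-fold in qM (5.28, adjusted p = 1.2e-07), each on 4 of 4 arrays. In ces-D it rose 3.05-fold (1.61, limma adjusted p = 0.0294), a call lost without ces-D 4°C replicate 1, 3 or 4 or ces-D 21°C replicate 1, 2 or 4 (1.57 to 1.61, adjusted p from 0.0519 to 0.0605), while without the array labelled wt 4°C replicate 4, which widens the shared spread, the adjusted p was 2.36e-13. LTI30 rose by 6.87 on the log2 scale in bri1-301, 6.49 in ces-D and 7.05 in qM, from 21°C levels near the lower end of the scale, so that the sizes are uncertain. KIN1 rose by 4.01, 4.64 and 4.78, COR15B by 5.0, 3.26 and 5.13, KIN2 by 4.50, 2.12 and 4.14, and COR47 by 2.35, 2.08 and 1.95 in the same order. All 6 COR genes passed in each mutant, and 6 adjusted over the list alone. The median of the list was 4.75 in bri1-301 (camera adjusted p = 5.64e-09), 2.69 in ces-D (1.31e-05) and 4.95 in qM (1.62e-08). In bri1-301 adjusted p = 0.265 with an estimated correlation, in ces-D 0.336 and in qM 0.265. These were 3.53e-06, 1.69e-05 and 3.53e-06 without the array labelled wt 4°C replicate 4.

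**Figure D2:**
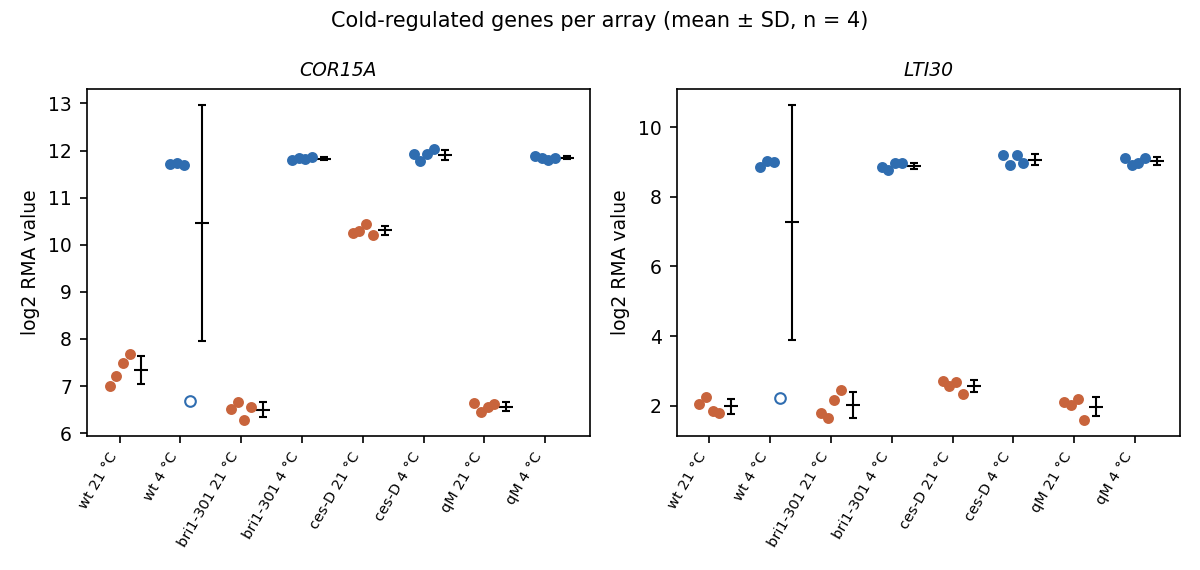
COR15A and LTI30 on each of the 32 arrays (log2 RMA value), orange at 21°C and blue at 4°C, with the mean ± SD of 4 arrays in black and the array labelled wt 4°C replicate 4 as an open symbol. COR15A was at 7.35 in wt and 10.3 in ces-D at 21°C, and LTI30 was at 2.21 on the open symbol.

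In bri1-301 4816 genes passed between the temperatures (2215 higher, 2601 lower at 4°C), in ces-D 5408 (2456 higher, 2952 lower) and in qM 4922 (2378 higher, 2544 lower). Higher genes were the more frequent with the arrays centred on their median in bri1-301 (2526 higher, 2254 lower) and ces-D (2733 and 2489), and in ces-D also with all probe sets tested (6554 and 5608). Of the genes past the threshold, 575, 838 and 672 changed at least 2-fold, against 627 in wt without the array labelled wt 4°C replicate 4. There were 5064, 5634 and 5181 without the array labelled wt 4°C replicate 4, which changes only the shared spread here. In that fit 1213 genes were higher and 1433 lower at 4°C in all 4 lines, and 75 passed in opposite directions in a pair of lines. The cold responses of wt and the mutants, which share no arrays, correlated across genes at r = 0.764 for bri1-301, 0.719 for ces-D and 0.852 for qM. Without that array these were 0.808, 0.759 and 0.886; genes are not independent replicates. Of genes past the threshold in both lines, 2270 moved the same way and 20 the opposite way in wt and bri1-301, where independent lists would share 518 in the same direction. For wt and ces-D these were 2355, 24 and 582, and for wt and qM 2703, 3 and 529. Without the array labelled wt 4°C replicate 4 the numbers in the same direction were 3260, 3313 and 3701, where independent lists would share 761, 847 and 778.

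EXPA8 fell in all 3 mutants (by 1.71 in bri1-301, 1.57 in ces-D and 2.56 in qM), and GI rose by 1.22, 1.14 and 1.08. EXO fell by 0.91 in bri1-301 and by 1.41 in qM, and in ces-D was at -0.47 (limma adjusted p = 0.0828, interaction adjusted p = 0.458). UGT73C6 and BIM1 fell in all 3, UGT73C6 by 1.41 and BIM1 by 0.66 in ces-D. The brassinosteroid-induced growth list passed in qM, with 3 of 4 lower, a median of -1.03 and a camera adjusted p = 0.0136. Its adjusted p = 0.265 with an estimated correlation, and 0.0344 without the array labelled wt 4°C replicate 4. In bri1-301 and ces-D 2 of 4 were lower and the list did not pass (camera adjusted p = 0.129 and 0.107). In ces-D all 3 photosynthesis genes were lower, LHCB4.2 at -1.14 (limma adjusted p = 2.18e-06), with a list median of -0.39 (camera adjusted p = 0.0337; without ces-D 4°C replicate 2, 0.0515), and adjusted p = 0.396 with an estimated correlation. All 3 were lower in qM as well and 1 in bri1-301, where the list did not pass (medians -0.37 and -0.26, camera adjusted p = 0.0989 and 0.233). PDF1.2, a defensin gene, fell by 1.09 in bri1-301, 1.67 in ces-D and 1.17 in qM, and no interaction for it passed (limma adjusted p = 0.422, 0.0751 and 0.591). The thionin gene THI2.1 fell by 1.58 in ces-D. In qM the flavonoid list did not pass (median 0.52, camera adjusted p = 0.291), and AT4G14090 was higher by 0.90 (limma adjusted p = 0.00826). EIN3 fell by 0.29, 0.31 and 0.27 in bri1-301, ces-D and qM, ATSPS4F rose by 0.92 in bri1-301 and 1.04 in qM, WRKY6 by 0.66 in ces-D and 0.68 in qM, STZ by 1.18 and BRL1 by 0.69 in qM, and SAG101 fell by 0.35 in bri1-301 (limma adjusted p from 9.86e-05 to 0.0125). In ces-D 3 of 4 flavonoid genes fell, with 4 adjusted over the list alone. DFR, which encodes dihydroflavonol reductase, fell by 2.27 (limma adjusted p = 1.28e-05), and the anthocyanin malonyltransferase gene AT5MAT by 1.09 (adjusted p = 0.00432). All 4 ces-D 4°C arrays lay below the 21°C range of DFR (7.26 to 7.75), but the arrays differed. AT5MAT was at 2.91 and 3.63 on replicates 1 and 3, and at 4.91 and 4.54 on replicates 2 and 4, against 4.92 to 5.39 at 21°C. Most of its fall was thus on replicates 1 and 3. AT4G14090 was at -0.75 (adjusted p = 0.0241), lost without ces-D 4°C replicate 1 or 3 or ces-D 21°C replicate 3 (adjusted p from 0.0974 to 0.182). The list's camera adjusted p was 0.0832 with a median of -0.92, and from 0.0135 to 0.0155 without ces-D 4°C replicate 2 or 4.

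At 21°C ces-D differed from wt most. The MADS-box gene PHE1 was higher by 5.65 ± 0.35 (limma adjusted p = 5.94e-13), AT1G14250 by 4.54 ± 0.20 (adjusted p = 2.26e-16), AT5G27220 by 3.35 and AT1G53080 by 3.34, beside CES. The resistance-type gene AT1G58602 was at -3.95 ± 0.56 (limma adjusted p = 6.6e-06), the TIR-NBS-LRR gene AT4G19500 at -3.40, AT5G22430 at -3.32, the receptor-like kinase gene AT1G51860 at -3.29 and AT5G44540 at -3.28. In each of these 10 genes all 4 ces-D arrays lay on one side of all 4 wt arrays. In total 1296 genes passed (722 higher, 574 lower), 279 of them at least 2-fold (156 higher, 123 lower), and 1545 (848 higher, 697 lower) without the array labelled wt 4°C replicate 4. With all probe sets tested the lower were the more frequent (1202 higher, 1264 lower).

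All 4 measured flavonoid and anthocyanin genes were higher in ces-D than in wt at 21°C, on all 4 arrays each, and 4 adjusted over the list alone. DFR was at 7.48 ± 0.20 against 5.37 ± 0.22 (SD, n = 4), 4.33-fold higher (log2 2.11 ± 0.37 SE, limma adjusted p = 0.000128). AT5MAT was higher by 1.71, the anthocyanin glucosyltransferase gene AT4G14090 by 1.61 and the glycosyltransferase gene UF3GT by 1.36 (limma adjusted p between 4.68e-05 and 0.0018). The list's median was 1.66 (camera adjusted p = 3.94e-06), and adjusted p = 0.265 with an estimated correlation. COR15A was 7.77-fold higher in unchilled ces-D (log2 2.96 ± 0.57, limma adjusted p = 0.000553), at 10.3 against 7.35. KIN2 (1.89, limma adjusted p = 0.0124) lost its call without wt 21°C replicate 2 (1.72, adjusted p = 0.0527). COR15B (1.81, limma adjusted p = 0.0334) lost it without wt 21°C replicate 1, 2 or 4 or any ces-D 21°C array (1.69 to 1.90, adjusted p from 0.0536 to 0.0981), and was at 6.12e-11 without the array labelled wt 4°C replicate 4. LTI30 (0.59, adjusted p = 0.789), COR47 (0.35, 0.561) and KIN1 (0.26) did not pass with all arrays, and LTI30 (0.00429) and COR47 (0.0418) passed without that array. Of the 6 COR genes 3 passed, and 3 adjusted over the list alone, with a median of 1.2 (camera adjusted p = 0.0222). The list's adjusted p = 0.534 with an estimated correlation, and 0.000139 without the array labelled wt 4°C replicate 4. Of the 3 jasmonate genes, THI2.1 was higher by 1.41 (limma adjusted p = 5.2e-08), JMT lower (-0.53, adjusted p = 0.0273) and PDF1.2 at 0.56 (adjusted p = 0.359), and the list did not pass (median 0.56, camera adjusted p = 0.302). JMT lost its call without wt 21°C replicate 1, 3 or 4 or ces-D 21°C replicate 1 or 2 (-0.53 to -0.41, limma adjusted p from 0.0569 to 0.153). EXO (-1.16, limma adjusted p = 0.000191) and WRKY6 (-0.63, adjusted p = 0.00929) were lower. The median of the genes upstream of the CBF genes was 0.02 (0.0173), where the test's direction was downward, and the list did not pass.

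**Figure D3:**
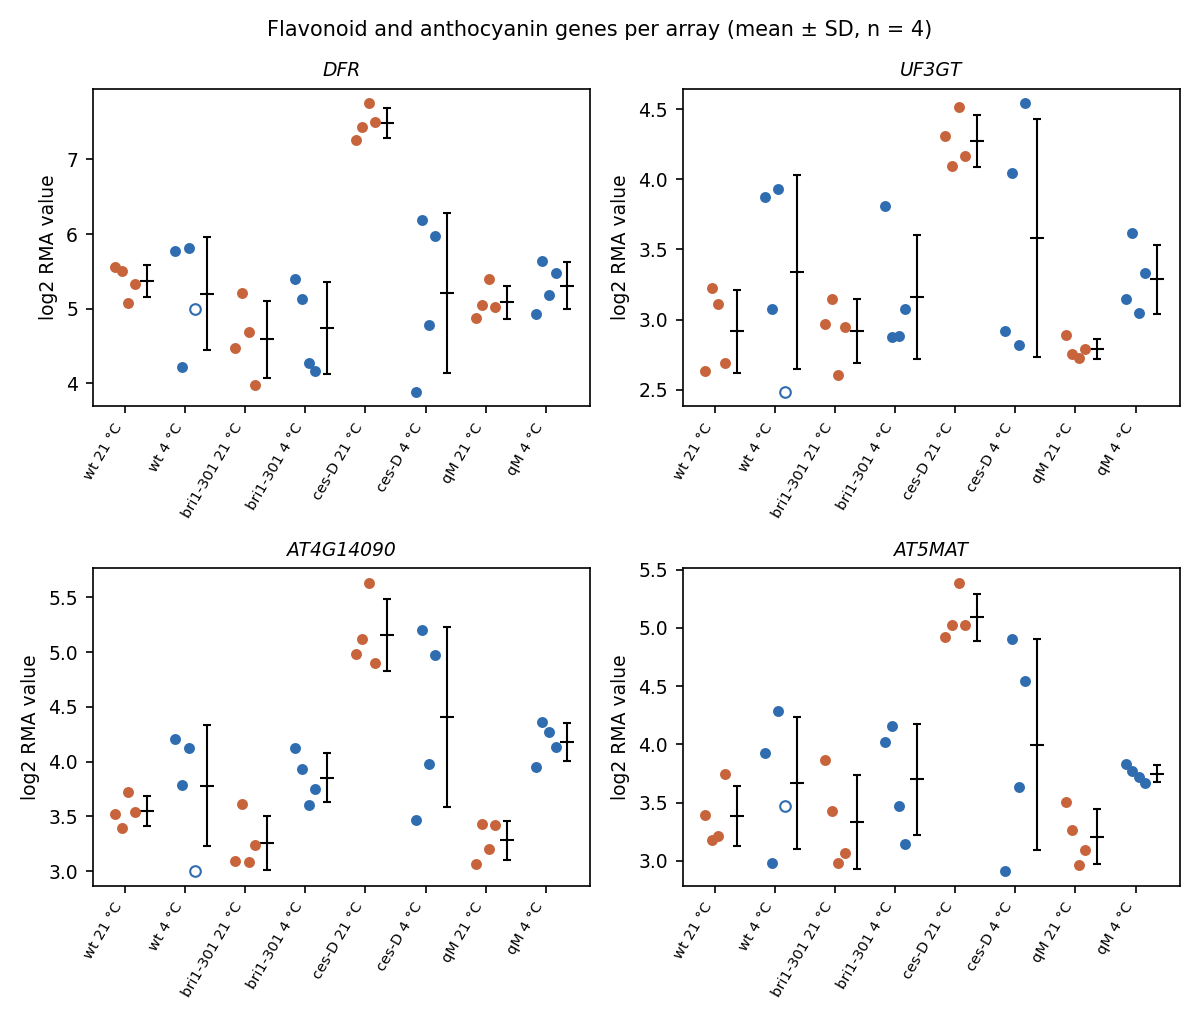
DFR, UF3GT, AT4G14090 and AT5MAT on each of the 32 arrays (log2 RMA value), orange at 21°C and blue at 4°C, with the mean ± SD of 4 arrays in black and the array labelled wt 4°C replicate 4 as an open symbol. At 21°C the 4 ces-D arrays lay above the 4 wt arrays for each gene, with DFR at 7.48 and 5.37.

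Few genes differed between bri1-301 and wt at 21°C. AT3G01345 was higher, at 10.05 ± 0.20 against 3.88 ± 0.91 (SD, n = 4; log2 6.17 ± 0.84 SE, limma adjusted p = 0.00018), the wt level being near the array medians, so that the size is uncertain. AT5G41740 was 8.14-fold higher (3.03 ± 0.49, limma adjusted p = 0.00174) and AT5G01740 higher by 0.75 (adjusted p = 0.00029). QQS, an orphan gene linked to starch, was 4.12-fold lower (-2.04 ± 0.19, limma adjusted p = 9.67e-08), and AT1G20150 (-1.45), AT2G20870 (-1.37) and AT3G63095 (-1.27, adjusted p = 1.09e-05) were lower. For each of these the arrays of the 2 lines did not overlap. AT5G57785 (1.32), the jacalin-related lectin gene JAL22 (0.79) and AT1G68875 (-1.78) lost their call with 1 array left out (limma adjusted p from 0.0696 to 0.243). For AT5G57785 this was any of the 8 compared arrays. For JAL22 it was wt 21°C replicate 2, 3 or 4 or bri1-301 21°C replicate 1, 2 or 3, and for AT1G68875 wt 21°C replicate 3 or 4 or bri1-301 21°C replicate 2, 3 or 4. COR15A was at -0.84 (limma adjusted p = 0.761) and at 1.11e-05 without the array labelled wt 4°C replicate 4. In total 27 genes passed (9 higher, 18 lower), 9 at least 2-fold. Without that array 61 passed (19 higher, 42 lower), among them all 27. The count was 17 without wt 21°C replicate 2, 12 without wt 21°C replicate 4 and 15 without bri1-301 21°C replicate 2, 3 or 4. No list passed with all arrays, and without the array labelled wt 4°C replicate 4 the COR list did (median -0.19, camera adjusted p = 0.000477, 0.0245 with an estimated correlation).

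At 21°C qM shared several of these differences from wt. AT5G41740 was 7.59-fold higher (2.93 ± 0.49, limma adjusted p = 0.00536). QQS (-1.80, adjusted p = 2.01e-06), AT1G20150 (-1.46, adjusted p = 0.000595) and AT3G63095 (-1.13, adjusted p = 0.000145) were lower. AT5G07230 (-1.07) lost its call without wt 21°C replicate 2 or 3 or qM 21°C replicate 1, 2 or 3, and RXF26 (-0.94) without wt 21°C replicate 2 or 4 or qM 21°C replicate 1 or 4 (limma adjusted p from 0.0575 to 0.2). In total 13 genes passed (1 higher, 12 lower), 6 of them at least 2-fold. Leaving out the array labelled wt 4°C replicate 4, there were 18 (4 higher, 14 lower), with COR15A then lower (-0.78, adjusted p = 9.99e-05, against 0.999 with all arrays). The count was 22 without wt 21°C replicate 1, 6 without wt 21°C replicate 2 or qM 21°C replicate 3, and 7 without wt 21°C replicate 4. No list passed with all arrays, and without the array labelled wt 4°C replicate 4 the COR list did (median -0.28, camera adjusted p = 0.00286, 0.0512 with an estimated correlation).

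**Figure D4:**
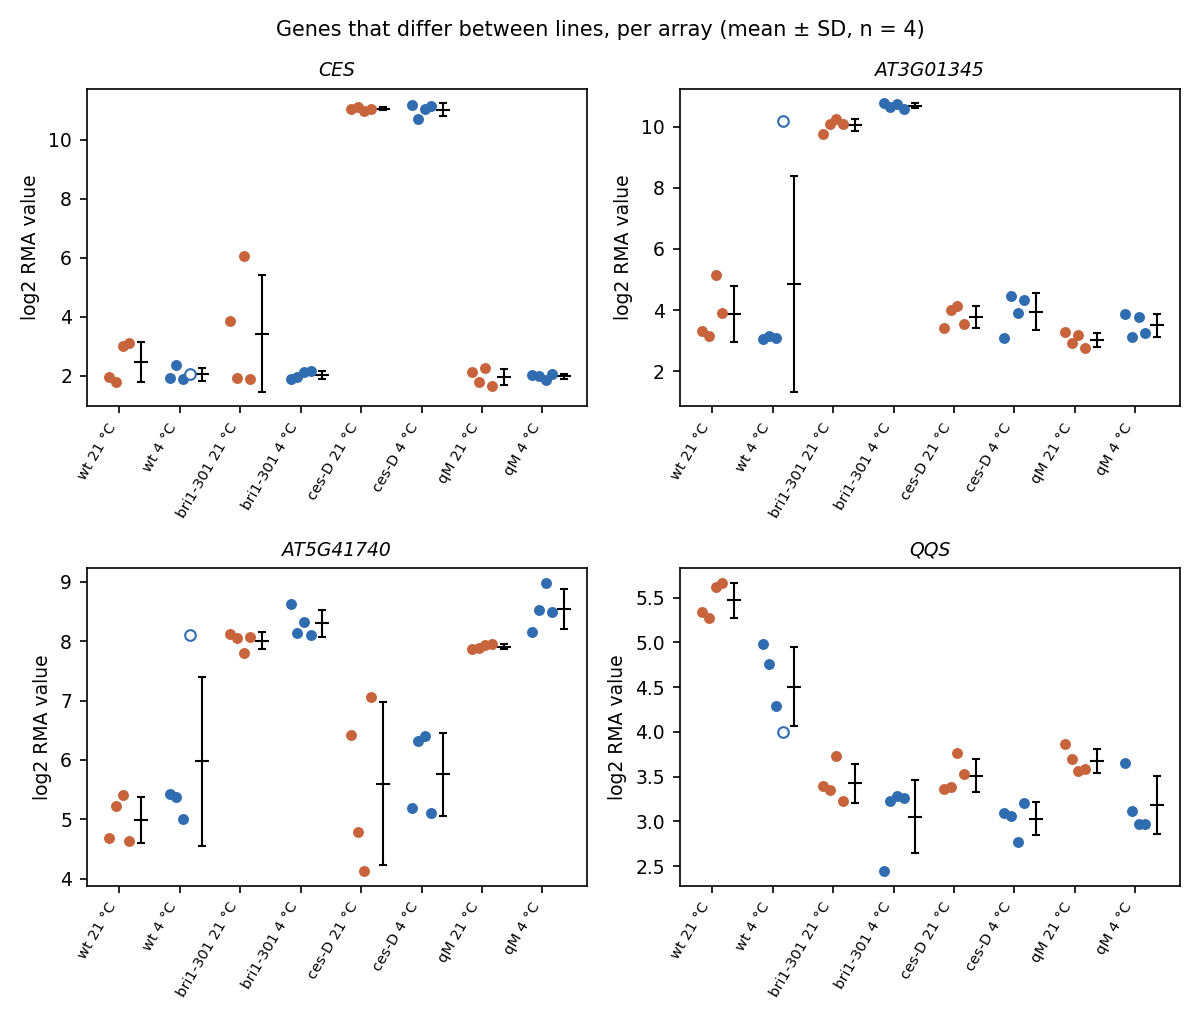
CES, AT3G01345, AT5G41740 and QQS on each of the 32 arrays (log2 RMA value), orange at 21°C and blue at 4°C, with the mean ± SD of 4 arrays in black. The open symbol is the array labelled wt 4°C replicate 4, at 10.2 for AT3G01345 and 8.10 for AT5G41740.

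At 4°C ces-D kept large differences from wt. PHE1 was higher by 5.24 ± 0.35, AT2G25964 by 3.29, AT5G27220 by 2.97 and AT1G57590 by 2.68, and lower were AT1G58602 (-3.93), the calmodulin-like gene CML41 (-3.33), AT4G20480 (-3.14), ZW9 (-3.14) and AT1G51860 (-3.11). In total 3234 genes passed (1585 higher, 1649 lower), 368 at least 2-fold. Higher genes were the more frequent with all probe sets tested (4156 higher, 3168 lower), with the arrays centred on their median (1762 and 1426) and, by less, with repeated quantile normalisation (1563 and 1523). There were 2765 without the array labelled wt 4°C replicate 4, of which 2320 were among the 3234. ZW9 was at -3.73 without that array. SAG101 (-0.70, limma adjusted p = 4.71e-06), SIZ1 (-0.35, adjusted p = 0.000319), PIF7 (-0.33, adjusted p = 0.00767) and STZ (-0.84, adjusted p = 0.0062) were lower. KIN1 (1.92, limma adjusted p = 0.00471) and COR47 (1.00, adjusted p = 0.00643) were higher, but by only 0.95 and 0.47 without that array. EXO (-0.76, limma adjusted p = 0.00839) lost its call without it (-0.44, adjusted p = 0.0607), and WRKY6 (-0.57, adjusted p = 0.0103) lost it without wt 4°C replicate 2 (-0.43, adjusted p = 0.0588). COR15A was at 1.45 (limma adjusted p = 0.072), at 0.20 (adjusted p = 0.238) without wt 4°C replicate 4, and from 1.86 to 1.88 (adjusted p from 0.0233 to 0.0259) without wt 4°C replicate 1, 2 or 3. Of the 6 COR genes 2 passed, and 6 adjusted over the list alone, with a median of 1.45 (camera adjusted p = 0.00512) and adjusted p = 0.441 with an estimated correlation. The median was 0.24 without the array labelled wt 4°C replicate 4 (camera adjusted p = 0.0413, and adjusted p = 0.164 with an estimated correlation). BRL1 (-0.68, limma adjusted p = 0.0171), LHCB4.2 (-0.49, adjusted p = 0.0307) and the reference gene AT2G28390 (0.26, adjusted p = 0.0428) lost their call with 1 array left out (adjusted p from 0.0504 to 0.186). For BRL1 this was wt 4°C replicate 1 or 2 or ces-D 4°C replicate 1 or 3 (-0.60 to -0.49). For LHCB4.2 it was wt 4°C replicate 2 or 4 or ces-D 4°C replicate 2 or 4 (-0.48 to -0.29), and for AT2G28390 wt 4°C replicate 1, 3 or 4 or any ces-D 4°C array (0.19 to 0.28). No flavonoid gene passed, DFR being at 0.01 (limma adjusted p = 0.99). This is a mean of unlike ces-D 4°C arrays, with DFR at 3.89 and 4.79 on replicates 1 and 3 and at 6.19 and 5.97 on replicates 2 and 4. The wt 4°C arrays were at 4.22 to 5.81.

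In bri1-301 at 4°C AT3G01345 was higher by 5.82 ± 0.84 (limma adjusted p = 0.000535), AT5G41740 by 2.32 (adjusted p = 0.00982), CIL by 1.24, AT3G16670 by 1.22 and AT5G46730 by 1.16. AT3G01345 was higher by 7.59 ± 0.31 (limma adjusted p = 1.48e-16) and AT5G41740 by 3.03 ± 0.41 (adjusted p = 0.000169) without the array labelled wt 4°C replicate 4. AT4G10860 (-1.70, adjusted p = 0.00575), AT5G59680 (-1.48), QQS (-1.45, adjusted p = 0.000123), the osmotin-like gene OSM34 (-1.42), AT1G44130 (-1.34) and SAG101 (-0.51, adjusted p = 0.00515) were lower. On the array labelled wt 4°C replicate 4 OSM34 was at 6.08 and AT4G10860 at 9.015, against means of 4.53 and 7.63 on the other 3 wt 4°C arrays. CIL was at 3.73 on it, against 4.65. The differences of these genes, and of AT5G46730, AT5G59680, AT1G44130 and SAG101, are thus smaller without it. Those of AT3G16670 and QQS (then -1.62, limma adjusted p = 7.45e-06) are larger. PDF1.2 was at -1.16 (limma adjusted p = 0.0325), lost without wt 4°C replicate 1, 2 or 4 or bri1-301 4°C replicate 2 or 4 (adjusted p from 0.0501 to 0.111). COR15A was at 1.37 (limma adjusted p = 0.178) and at 0.11 (adjusted p = 0.674) without the array labelled wt 4°C replicate 4. In total 554 genes passed (167 higher, 387 lower), 28 at least 2-fold (6 higher, 22 lower). Without that array there were 347 (135 higher, 212 lower), 223 of them among the 554, and 18 at least 2-fold (5 higher, 13 lower). The count was 876 without wt 4°C replicate 1, 1028 without wt 4°C replicate 3 and 138 without bri1-301 4°C replicate 2. No COR gene passed with limma, where 6 did adjusted over the list alone. Their median was 1.17 (camera adjusted p = 0.00175), with adjusted p = 0.401 with an estimated correlation, and without the array labelled wt 4°C replicate 4 it was 0.09 (camera adjusted p = 0.527).

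At 4°C 1 gene passed between qM and wt, QQS (-1.33 ± 0.19, limma adjusted p = 0.00117), and 1994 had an unadjusted p under 0.05. Without the array labelled wt 4°C replicate 4 there were 3, QQS (-1.50), AT5G41740 (3.27, limma adjusted p = 4.97e-05, against 0.0704) and AT5G56890 (0.97, adjusted p = 9.06e-06, against 0.197), and 1350 at an unadjusted p under 0.05. Without wt 4°C replicate 1 there were 32. No COR gene passed with limma, where 4 did adjusted over the list alone, and the list's median was 1.26 (camera adjusted p = 3.5e-05). Its adjusted p = 0.336 with an estimated correlation, and without the array labelled wt 4°C replicate 4 the median was 0.10 (camera adjusted p = 0.127). No brassinosteroid-induced growth gene passed, 3 were lower adjusted over the list alone, and the list's median was -0.47 (camera adjusted p = 0.0203), with adjusted p = 0.281 with an estimated correlation. That call was lost without wt 4°C replicate 1 or 4 or qM 4°C replicate 3 (camera adjusted p from 0.07 to 0.0978), and without wt 4°C replicate 4 the median was -0.22.

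Cold responses that differed from that of wt were tested as interactions. For ces-D AT1G14250 (-3.85 ± 0.29, limma adjusted p = 4.96e-10), JAL23 (-3.07, adjusted p = 0.00112), AT5G19110 (-2.43, adjusted p = 6.21e-08), DFR (-2.11 ± 0.52, adjusted p = 0.022), AT2G32150 (-1.95, adjusted p = 0.000615) and THI2.1 (-1.49, adjusted p = 0.000136) responded lower than in wt, and AT5G62210 (2.81, adjusted p = 0.00215) and AT5G44540 (2.65, adjusted p = 0.00316) higher. AT3G09450 (1.93) lost its call without ces-D 4°C replicate 2 or 4, wt 21°C replicate 2 or ces-D 21°C replicate 4 (limma adjusted p from 0.0523 to 0.0587). AT2G23910 (1.97) lost it without ces-D 4°C replicate 2 or 4, wt 21°C replicate 2, 3 or 4 or any ces-D 21°C array, and AT1G68875 (1.93) without wt 4°C replicate 2, ces-D 4°C replicate 1, 2 or 4, wt 21°C replicate 3 or 4 or any ces-D 21°C array (adjusted p from 0.0524 to 0.0992). JAL23 was at -2.36, AT2G23910 at 1.24 and AT3G09450 at 1.26 without the array labelled wt 4°C replicate 4. PIF7 (-0.46, limma adjusted p = 0.0353) and SAG101 (-0.49, adjusted p = 0.0448) lost their call with 1 array left out (adjusted p from 0.0509 to 0.0934), PIF7 without wt 4°C replicate 1, ces-D 4°C replicate 4, wt 21°C replicate 2, 3 or 4 or ces-D 21°C replicate 1, 3 or 4, and SAG101 unless it was wt 4°C replicate 1 or 3, ces-D 4°C replicate 1, wt 21°C replicate 2 or ces-D 21°C replicate 1. In total 575 genes passed (258 higher, 317 lower), 136 at least 2-fold. Higher genes were the more frequent with all probe sets tested (745 higher, 596 lower) and with the arrays centred on their median (295 and 262). There were 547 without the array labelled wt 4°C replicate 4, 394 of them among the 575. The count was 911 without wt 4°C replicate 1, 318 and 303 without ces-D 4°C replicates 2 and 4, 307 and 298 without wt 21°C replicates 3 and 4, and 329 without ces-D 21°C replicate 3. Of the flavonoid genes 1 passed, and 4 adjusted over the list alone, with a median of -1.24 (camera adjusted p = 0.00543) and adjusted p = 0.336 with an estimated correlation. The ces-D 4°C arrays differed, with AT4G14090 at 3.47 and 3.98 on replicates 1 and 3 and at 5.21 and 4.98 on replicates 2 and 4. Its ces-D 21°C arrays were at 4.90 to 5.64. The other flavonoid genes were also lower on replicates 1 and 3 than on replicates 2 and 4. AT5MAT was at -1.37 (limma adjusted p = 0.0614), UF3GT at -1.12 (0.117) and AT4G14090 at -0.99 (0.12), and the last 2 passed without the array labelled wt 4°C replicate 4 (0.0425 and 0.0412). Without that array COR15A (-2.76 ± 0.15, limma adjusted p = 2.64e-13), COR15B (-1.54, adjusted p = 3.06e-05) and KIN2 (-1.69, adjusted p = 0.00506) responded lower in ces-D, where with all arrays COR15A was at -1.51 (adjusted p = 0.296) and COR15B at -0.37 (adjusted p = 0.821). The COR list's median was then -1.01 (camera adjusted p = 0.00033, 0.0232 with an estimated correlation), against 0.14 (0.477) with all arrays. In the fit without that array COR15A in ces-D was above wt at 21°C (2.96). At 4°C COR15A was at 11.77 to 12.02 on the ces-D arrays and at 11.69 to 11.74 on wt replicates 1 to 3. Its lower response thus goes with the higher 21°C level, not with a lower 4°C level.

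For bri1-301 AT4G10860 (-2.54 ± 0.47, limma adjusted p = 0.0143) and AT1G61080 (-1.74, adjusted p = 0.00892) responded lower than in wt, and AT1G20150 (1.45, adjusted p = 0.0194) and CIL (1.38, adjusted p = 0.0159) higher. Without the array labelled wt 4°C replicate 4, AT1G20150 in bri1-301 differed from wt by -1.45 at 21°C and by -0.009 at 4°C. Its wt 4°C level was 2.08 ± 0.24 (SD, n = 3), near the lower end of the scale. Its interaction thus goes with the 21°C difference, and a different response to cold is uncertain. The other 6 genes taken by the rule lost their call with 1 array left out (limma adjusted p from 0.05 to 0.0876). For AT5G57785 (-1.93) this was wt 21°C replicate 4 or bri1-301 21°C replicate 1. For AT4G22485 (1.76) it was also wt 4°C replicate 2 or wt 21°C replicate 1. For AT5G46600 (1.37) it was bri1-301 4°C replicate 2, wt 21°C replicate 1 or bri1-301 21°C replicate 1 or 4. For OSM34 (-1.77) it was bri1-301 4°C replicate 2 or 4, wt 21°C replicate 3 or 4 or bri1-301 21°C replicate 1 or 2. For AT1G52750 (1.28) it was wt 4°C replicate 2, bri1-301 4°C replicate 2 or 4, wt 21°C replicate 3 or 4 or bri1-301 21°C replicate 2 or 4. AT1G33950 (-1.81) kept its call only where wt 4°C replicate 1, 3 or 4, bri1-301 4°C replicate 1 or bri1-301 21°C replicate 3 was the array left out. In total 105 genes passed (38 higher, 67 lower), 33 at least 2-fold, and 155 (82 higher, 73 lower) without the array labelled wt 4°C replicate 4, 84 of them among the 105. The count was 286 and 171 without wt 4°C replicates 1 and 3, and 176, 47 and 46 without bri1-301 4°C replicates 1, 2 and 4. It was 44, 40 and 25 without wt 21°C replicates 1, 3 and 4, and 29, 46, 210 and 43 without bri1-301 21°C replicates 1 to 4. No COR gene passed with limma, where 3 did adjusted over the list alone. Their median was 1.48 (camera adjusted p = 0.000957), with adjusted p = 0.396 with an estimated correlation. Leaving out the array labelled wt 4°C replicate 4, it was 0.29 (camera adjusted p = 0.00709, 0.0673 with an estimated correlation), and COR15A passed at 0.95 ± 0.15 (limma adjusted p = 0.00491, against 2.21 and 0.185). In that fit COR15A in bri1-301 was below wt at 21°C (-0.84) and near it at 4°C (0.11). For the brassinosteroid-induced growth genes the median was -0.03 and the mean -0.02, the test's direction was upward, and the list did not pass.

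For qM 1 gene passed as an interaction, AT5G50010 (0.95 ± 0.16, limma adjusted p = 0.0213), and 1433 had an unadjusted p under 0.05. There was none without wt 4°C replicate 2, qM 4°C replicate 4, wt 21°C replicate 3 or 4 or qM 21°C replicate 1 or 2 (AT5G50010 then at an adjusted p from 0.0539 to 0.0993). There were 2 without wt 4°C replicate 1, 3 without wt 4°C replicate 3 or wt 21°C replicate 1, and 4 without qM 21°C replicate 4. Without the array labelled wt 4°C replicate 4 there were 3, AT5G50010, the MADS-box gene AGL24 (0.83, limma adjusted p = 0.0105, against 0.497) and COR15A (0.91, adjusted p = 0.0105, against 2.17 and 0.497), and 1174 at an unadjusted p under 0.05. In that fit COR15A in qM was below wt at 21°C (-0.78) and near it at 4°C (0.13). No COR gene passed with limma with all arrays, where 2 did adjusted over the list alone. The list's median was 1.63 (camera adjusted p = 0.000136), with adjusted p = 0.336 with an estimated correlation. Without the array labelled wt 4°C replicate 4 it was 0.33 (camera adjusted p = 0.000524, 0.0245 with an estimated correlation).

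The mutants' differences from wt were set against each other across genes, which are not independent replicates. At 21°C bri1-301 and qM shared 8 genes, all in the same direction: AT1G02190, AT1G44970, AT1G20150, AT2G41415, QQS, AT3G63095, CSLA01 and AT5G41740. Independent lists would share 0.0136, and without the array labelled wt 4°C replicate 4 they shared 13. Their fold changes correlated at r = 0.498, where unchanged groups against shared wt arrays gave 0.499, with a covariance of 0.0131 against a simulated 0.0107, and r = 0.183 and 0.00606 with the wt arrays split. For bri1-301 and ces-D at 21°C r was 0.259 (simulated 0.499), the covariance 0.0145 (0.0107), and with split arrays 0.118 and 0.00754. They shared 18 genes in the same and 2 in opposite directions, where independent lists would share 1.02, and 33 and 9 against 2.74 without the array labelled wt 4°C replicate 4. For ces-D and qM at 21°C r was 0.221 (simulated 0.501), the covariance 0.0107 (0.0107), with split arrays 0.0651 and 0.00366, and 11 genes were shared in the same direction against 0.46 (13, with 2 in opposite directions, against 0.794 without that array).

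At 4°C bri1-301 and ces-D had r = 0.555 (simulated 0.501), a covariance of 0.0489 (0.0107) and, with the wt arrays split, 0.239 and 0.0263. They shared 379 genes in the same and 8 in opposite directions, where independent lists would share 54.5, and 223 and 5 against 29.1 without the array labelled wt 4°C replicate 4. Without that array r was 0.511, below the simulated 0.572, and the covariance 0.0409 (0.0125). For bri1-301 and qM r was 0.621 (simulated 0.498) and the covariance 0.028 (0.0106), with split arrays 0.0906 and 0.00546, and without that array r was 0.549, below the simulated 0.571, and the covariance 0.0199 (0.0125). For ces-D and qM r was 0.423 (simulated 0.5) and the covariance 0.0306 (0.0107), with split arrays 0.0877 and 0.00807, and without that array r was 0.346 (simulated 0.572) and the covariance 0.0205 (0.0125). Each split at 4°C set that array against a single mutant of the pair, so the mutants were compared with unlike wt arrays. No split was made without it. The low split values at 4°C therefore cannot be put down to the sharing of wt arrays alone. QQS was the 1 gene shared in each of the pairs with qM (3 and 1 without that array). Between 21°C and 4°C, where no arrays are shared, the effects of ces-D correlated at r = 0.56, with 728 genes in the same and 12 in opposite directions, where independent lists would share 126 (792 and 16 against 129 without that array). For bri1-301 r was 0.0531, with AT1G31690, AT3G01345, QQS and AT5G41740 past the threshold in the same direction at both temperatures, against 0.512 (6, with 1 in the opposite direction, against 0.693 without that array), and for qM r was 0.0269, with QQS (3 without that array). Both r changed sign with Spearman's correlation (-0.025 and -0.018).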

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

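The 3 tests on the array labelled wt 4°C replicate 4 were chosen after its values were seen, while the splits of the arrays and the interactions were planned. Among 128 groups of 4 arrays (16 measures in 8 groups), 12 held an array far from the other 3, where about 1 in 20 groups would by chance, and 8 of the 12 were on this array. These 8 overlap, being the first component, the mean of the COR genes and the COR genes themselves. They count as 1 observation more than as 8, so 12 of 128 cannot be set against 1 in 20 as an excess. Its first principal component was -25.45, against 22.7 to 29.09 on the other 3 wt 4°C arrays, and its mean over the COR genes was 5.218, against 9.561 to 9.648. COR15A was at 6.69 on it (others 11.69 to 11.74), COR15B at 4.985 (9.542 to 9.879), COR47 at 8.368 (10.43 to 10.57), KIN1 at 2.76 (6.375 to 6.822), KIN2 at 6.295 (10.01 to 10.35) and LTI30 at 2.21 (8.84 to 9.033).

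For this array labels exchanged with an array labelled 21°C are argued against, since the highest COR mean of those arrays was 6.67, below the 9.56 of the lowest other array labelled 4°C. Unchilled wt plants are argued against as well: of 61 genes past the threshold between bri1-301 and wt at 21°C without it, it lay nearer the bri1-301 mean at 52, where the 4 wt 21°C arrays did so at 2 to 13 and the 4 bri1-301 21°C arrays at 56 to 61. The wt and bri1-301 21°C arrays helped to choose the 61 genes, which widens the gap between their ranges, and this array did not. Its 52 lying below 56 therefore does not count against bri1-301 plants. RNA of bri1-301 plants kept at 21°C remains a candidate source but is not settled. AT3G01345 was at 10.17 on it, within the 9.77 to 10.76 of the 8 bri1-301 arrays. QQS was at 3.99, above their 2.44 to 3.73 and below the 4.29 to 5.66 of the other 7 wt arrays. At 21°C alone QQS was nearer the 3.23 to 3.73 of bri1-301 than the 5.27 to 5.66 of wt, but outside both. It is not a copy of another array, as the SD of its differences to the nearest 21°C array was 0.272, above the 0.220 of the closest pair of arrays. No biological explanation was tested, and the array stayed in its labelled group.

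The other 4 arrays far from their group were bri1-301 21°C replicate 3 on the first component, at -23.88 (others -25.38 to -25.33), and ces-D 21°C replicate 3 in the mean of the flavonoid genes, at 5.821 (5.368 to 5.418). The others were qM 21°C replicate 3 in the photosynthesis genes, at 9.382 (9.541 to 9.558), and ces-D 21°C replicate 1 in the jasmonate genes, at 3.901 (4.261 to 4.283).

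Cold responses differed from that of wt by the interaction test at 105 genes in bri1-301, 575 in ces-D and 1 in qM. The COR list differed in bri1-301 with a median of 1.48 and in qM with a median of 1.63, and the flavonoid list in ces-D with a median of -1.24, by camera with the preset correlation. None of the 3 passed with all arrays with an estimated correlation (adjusted p = 0.396, 0.336 and 0.336), and without the array labelled wt 4°C replicate 4 the COR medians were 0.29 and 0.33 and the flavonoid median -1.42.

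Other splits of the same arrays were counted for each result, the real one included. For the cold responses 1 of 35 splits gave as many genes, the real one: 3554 in wt (highest other 2867), 4816 in bri1-301 (161), 5408 in ces-D (16) and 4922 in qM (1). This is under the 1 in 20 set beforehand, and 1 of 35 is the lowest share that 35 splits can give. At 21°C it was also 1 of 35, with 27 genes in bri1-301 (highest other 1), 1296 in ces-D (2) and 13 in qM (9). At 4°C it was 1 of 35 for bri1-301, with 554 genes (541), and for ces-D, with 3234 (838), but 4 of 35 for qM, with 1 gene (1), where chance is not excluded. Of 100 splits drawn for each interaction, 1 gave as many genes for bri1-301 (105, highest other 18) and 3 for ces-D (575, highest others 1667 and 746), a share under 1 in 20. The split with 1667 exchanged 1 array of each line at 21°C and all 4 at 4°C, which adds up line effects instead of subtracting them and so points to a structure of the samples. The split with 746 exchanged 2 arrays of each line at 21°C and 0 at 4°C, which leaves the line difference at 4°C in the contrast. For the interaction of qM 6 of 100 splits gave as many (1 gene, highest other 3), and for the number of list tests passed 5 of 100 did (17, highest other 22), so chance is not excluded for these.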

How the results depend on the processing

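Leaving the array labelled wt 4°C replicate 4 out of contrasts without wt 4°C arrays was chosen after the data were seen; all other settings were planned. The 23 results that answer a comparison had 210 values under 19 other settings, of which 67 moved and 143 did not (counts within 1.5 times, agreements within 1 jackknife standard error), and 286 values with 1 array left out, of which 46 moved. Agreements near 0 changed sign: between temperatures that of bri1-301 (0.053) was -0.025 and that of qM (0.027) -0.018 with Spearman's correlation, and with 1 array left out they reached -0.022 and -0.008. Repeated quantile normalisation and leaving out the dimmest 25% of genes (12415 kept) moved none of the 23. Median centring and the mean of all probe sets moved none of the 14 counts they were run on by over 1.5 times, and were not run on the 9 agreements. Median centring turned which direction was the more frequent in 5 of the 13 contrasts and the larger set of probe sets in 5, among them qM at 4°C (6 higher and 5 lower). Array weights did so in 3, an adjusted p under 0.01 in 2, and 2-fold, dim genes left out, only the compared groups, the ordinary t-test and repeated quantile normalisation in 1 each. A background correction and a slide or scan batch, both planned, could not be run on summarised values, and signal over background, which limits dim genes, was not assessed. The stricter thresholds and the larger set of probe sets change counts by construction. The ordinary t-test and the fits of only the compared groups have fewer degrees of freedom for the spread. That alone does not account for the fall in the wt cold response, since neither setting moved the cold responses of bri1-301, ces-D and qM by over 1.5 times. Fitting only the compared groups moved 7 counts, all of contrasts that use the wt 4°C arrays. For the other changes the cause was not tested.

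In the order wt, bri1-301, ces-D and qM, the cold responses had 6592, 9909, 12162 and 9827 probe sets past the threshold when all were tested, and 303, 575, 838 and 672 genes at least 2-fold. For wt there were 1852 at an adjusted p under 0.01, 480 with only the compared groups in the fit and 2 with an ordinary t-test. At 21°C bri1-301, ces-D and qM had 41, 2466 and 21 with all probe sets, 9, 279 and 6 at least 2-fold and 12, 829 and 7 at an adjusted p under 0.01. With array weights bri1-301 had 130 and qM 58, and with an ordinary t-test 5 and 4. At 4°C they had 843, 7324 and 11 with all probe sets and 0, 1105 and 0 with only the compared groups. An ordinary t-test gave 0, 528 and 0. At least 2-fold were 28 in bri1-301 and 368 in ces-D, and at an adjusted p under 0.01 86 and 1867. Array weights gave 96 for bri1-301 and 4 for qM, and an intensity trend with robust variances 2 for qM. The interactions of bri1-301, ces-D and qM had 33, 136 and 0 at least 2-fold, 4, 113 and 0 at an adjusted p under 0.01, and 8, 204 and 0 with only the compared groups. With all probe sets ces-D had 1341 and qM 0, and qM had 2 with array weights and 0 with an intensity trend and robust variances. Of the list tests 0 passed with an estimated correlation, 33 with directional fry and 0 with mixed fry, where 17 passed with the preset one. With Spearman's correlation the agreement of the ces-D effect at 21°C and 4°C was 0.277, and that of ces-D and qM at 21°C 0.307. Over genes past the threshold in a comparison alone, the agreement between temperatures was 0.294 for bri1-301, 0.67 for ces-D and 0.941 for qM. With the wt arrays split the agreement at 21°C and 4°C was 0.118 and 0.239 for bri1-301 and ces-D, 0.183 and 0.091 for bri1-301 and qM, and 0.065 and 0.088 for ces-D and qM. At 4°C a single side of each split held the array labelled wt 4°C replicate 4.

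With 1 array left out the counts ranged from 2210 to 4972 for the cold response of wt, 4121 to 5064 for bri1-301, 4767 to 5634 for ces-D and 4322 to 5181 for qM. At 21°C they ranged from 12 to 61 for bri1-301, 1025 to 1545 for ces-D and 6 to 22 for qM, and at 4°C from 138 to 1028, 2469 to 3480 and 1 to 32. For the interactions they ranged from 25 to 286, 298 to 911 and 0 to 4, and from 15 to 18 for the list tests. The agreement of bri1-301 and ces-D ranged from 0.223 to 0.304 at 21°C and 0.509 to 0.618 at 4°C, that of bri1-301 and qM from 0.44 to 0.551 and 0.549 to 0.714, and that of ces-D and qM from 0.202 to 0.268 and 0.346 to 0.515. Between temperatures it ranged from -0.022 to 0.1 for bri1-301, 0.527 to 0.568 for ces-D and -0.008 to 0.051 for qM. Of 243 named gene results, 193 values with another array left out lost their call and 3 gained one. Without the array labelled wt 4°C replicate 4, 5 lost it and 17 gained it. Named genes lost their call in 48 cases at an adjusted p under 0.01, 62 at 2-fold, 103 with the ordinary t-test, 81 with only the compared groups, 16 with all probe sets, 8 with an intensity trend, 7 with array weights, 5 with quantile normalisation and 4 with median centring.

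With the replicate number as a replicate block the counts were 3451, 4720, 5324 and 4844 for the cold responses, 22, 1246 and 10 at 21°C, 496, 3219 and 1 at 4°C and 72, 514 and 1 for the interactions, with 17 list tests passed. No total moved by over 1.5 times, but by direction the genes higher in bri1-301 at 21°C went from 9 to 5 and the lower genes of its interaction from 67 to 41, and 9 named genes lost their call. The numbers do not pair the arrays: deviations of same-numbered arrays from their group means correlated at -0.35 to 0.167 (mean -0.00317, other numbers 0.00106), and 5 of 32 arrays matched their own number best.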

Other observations

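The tests of gene families, of the placement of ces-D genes along chromosomes and of probe sets shared by neighbouring copies, the count of these genes next to CES, and the count in ces-D with the wt arrays split or in simulated groups, were chosen after the data were seen. Genes sharing the letters of their symbol were tested as families with camera (37 families, 481 tests, 13 passed with the preset correlation). None of the 13 passed with an estimated correlation (adjusted p from 0.883 to 0.884). Subunit genes of RNA polymerase II (NRPB) were higher in the cold in ces-D, 7 of 9 past the threshold, with a median of 0.60 (camera adjusted p = 0.00344, and adjusted p = 0.883 with an estimated correlation). NRPB9B rose by 1.13 ± 0.20 (limma adjusted p = 5.55e-05), NRPB12 by 0.91 and NRPB7 by 0.86 in ces-D, and NRPB9B also by 0.95 in bri1-301, 1.41 in qM and 0.64 in wt. The IQD genes, which encode calmodulin-binding proteins, were lower in the cold in wt, 5 of 17 past the threshold, with a median of -0.19 (camera adjusted p = 0.0275, and adjusted p = 0.883 with an estimated correlation). IQD19 fell by 1.87 ± 0.29 in wt (limma adjusted p = 6.97e-05), by 1.76 in bri1-301, by 1.64 in ces-D and by 2.39 in qM. IQD18 fell by 0.60 in wt, and was higher in ces-D than in wt by 1.15 at 21°C (limma adjusted p = 2.81e-05) and by 1.72 at 4°C (adjusted p = 1.98e-08).

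Differences of the 63 plastid-encoded genes were small. In the cold response of wt 11 were lower and none higher past the threshold, with a median of -0.09 (camera adjusted p = 1.07e-05, and adjusted p = 0.883 with an estimated correlation). Examples were rps18 (-0.47, limma adjusted p = 0.00158), rps16 (-0.42, adjusted p = 0.00353) and psbM (-0.42, adjusted p = 0.00537). The mutants' cold responses did not pass: the median was -0.0016 in bri1-301 (1 higher and 2 lower, camera adjusted p = 0.987), -0.027 in ces-D (3 and 3, adjusted p = 0.965) and -0.026 in qM (1 and 6, adjusted p = 0.506). At 21°C these genes were lower than in wt in all 3 mutants, with medians of -0.044 in bri1-301 (camera adjusted p = 1.07e-05), -0.040 in ces-D (adjusted p = 0.0245) and -0.028 in qM (adjusted p = 0.0124), and at 4°C higher in bri1-301 (0.05, adjusted p = 0.0305), with no single gene past the threshold. The interactions had medians of 0.09 in bri1-301 (camera adjusted p = 2.08e-06), 0.07 in ces-D (adjusted p = 7.53e-05) and 0.06 in qM (adjusted p = 0.000474), with 1 gene past the threshold in ces-D. None of these 7 passed with an estimated correlation (adjusted p = 0.883 to 0.884 with an estimated correlation). The cold response of wt, the differences at 21°C and the interactions all use the same 4 wt 21°C arrays, so they are not independent of each other.

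Genes that differed between ces-D and wt at both temperatures by at least 2-fold (149, 75 higher and 74 lower) lay together on chromosome segments more often than random placements. In 10000 random placements the highest number among 100 consecutive tested genes was 9 (median 5), where the real one was 11, from AT4G16000 to AT4G17245, with AT4G16215 higher (1.67 at 21°C) and 10 lower, among them the TIR-NBS-LRR genes AT4G16900 (-1.83) and AT4G16960 (-1.03). That window was chosen after the positions were seen, and 8 adjacent pairs against at most 7 (median 1) at random argue the same way against chance placement. The window could not come from higher transcription of the genes next to CES (AT1G25330), which by its locus name lies on another chromosome. For the adjacent pairs such transcription is argued against, since 0 of the 20 nearest tested genes of CES were among the 149. The median of the 20 was 0.087 at 21°C, although 4 were higher past the threshold there (AT1G25320 by 1.56, IDD16 by 0.76, AT1G25300 by 0.74 and AT1G25500 by 0.45), 1 was lower and 10 passed at 4°C. Probe sets shared by neighbouring copies cannot be told apart from other sources, since keeping 1 gene per run left at most 4 in a window but caps that count by construction, and a linked genomic difference in the ces-D line may also be the source but was not tested.

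bri1-301 and qM shared differences from wt at 21°C, 8 genes with all arrays and 13 without the array labelled wt 4°C replicate 4. A difference of the wt plants or stock from all 3 lines is argued against as the whole source, since AT1G06360 (-0.49) and COR15A (2.96) went the opposite way in ces-D, and AT5G56890 was at 0.003 there against 0.63 in bri1-301 and 0.68 in qM. As the source of part of them it stays open. ces-D differed in the same direction at 9 of the 13, but shared wt arrays favour this, as genes chosen that way in simulated unchanged groups gave 8.1. With 2 wt arrays choosing the genes and the other 2 set against ces-D, it did so at 29 of 59 summed over 6 splits. Of the rest, 6 went the opposite way, 1 in each split, and 24 did not pass. These are not 59 separate genes, as the splits share arrays. COR15A, QQS, AT3G63095 and AT5G41740 were chosen in all 6. Chance values of the shared wt arrays that are independent between genes are argued against as the source of the 13 genes. Simulated unchanged groups with such normal values shared 0.0571 on average. Wt arrays that deviate together over many genes were not simulated and stay open. The number of shared genes went from 4 to 21 with the 2 wt arrays that chose them. For the agreement over all tested genes, chance values of the shared wt arrays cannot be told apart. The covariance was 0.00606 with the wt arrays split and 0.0131 with them shared, between the bounds set beforehand. Effects of brassinosteroid signalling common to both mutants stay open and were not tested.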
